A study of Arabidopsis thaliana with 10 samples.

How the data were processed

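PARE libraries were made from total RNA of rosette leaves of 21-day-old plants, per the labels' protocols. The authors deposited 1 file per library with tag sequences of 20 or 21 nt and their counts, which are whole read counts that were not normalised, as their differing totals show. The trimming and counting software is not given in the sources used here, and no file gives a gene or a genome position. Grouping followed the genotype in the labels, with 2 libraries for each of 5 genotypes. Total counts per library are given with the results. A tag with no read in a group is bounded by 3 counts over that group's libraries, and a share of reads by the spread between both libraries. Reads of one tag carry no molecular identifiers and may be PCR copies.

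From the deposited counts, tags were cut to their first 20 nt and summed, and the 261954 tags with at least 200 reads over all libraries (50.5% of all reads) were kept for tag-level tests, of which 261951 passed the filter filterByExpr. Tests used edgeR 4.0.16 in R 4.3.3: a quasi-likelihood fit of all 10 libraries by genotype, TMM factors on the full library totals, and Benjamini-Hochberg adjusted p under 0.05. TMM factors were 1.30 and 1.29 for WT and 0.500 and 0.479 for fry1-6, so that fry1-6 counts are scaled up against WT. The common dispersion was 0.119. Shares of reads were tested by exact permutation over all ways to put 10 libraries into 5 pairs, with the variance between pair means over that within pairs as the statistic. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9; DESeq2 1.42.0 was an alternative.

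The planned tests on genes, introns, windows downstream of genes, 3′ UTR sites, exon junctions, reading frame and transcript starts, the gene lists and the check of the mutated genes all need a genome and were not run; tags took their place. The choice of tags, and the classes below, were made after the data were seen, whereas the list of miRNAs, the comparison of fold changes with fry1-6 and the grouping were fixed before the data were examined. The search for miRNA sites and the stop codon share were planned and then changed after the data were seen, as given below. The named-tag rule carries over the rule written for genes: the 8 that rose and the 8 that fell most among tags with adjusted p under 0.05, a mean CPM of at least 5 over the 4 libraries compared and both mutant libraries beyond both WT libraries. Since no table used here pairs tags with genes, at most 2 tag sequences that rose and 2 that fell are printed per mutant. Sites of a miRNA are given without their sequence. For miRNA sites the rule took the 6 that rose and the 3 that fell most with a mean CPM of at least 0.5.

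The 5′ splice site class, its U12-type and GC forms, the TGTANATA class and the adenine class were found by looking through hexamers in these data, and are reported as such. Rearranged hexamers (all orders of the same bases that do not start with GT, nor with GC for the GC form) served as controls for the 5′ splice site class and its GC form. Motifs with 1 base changed were the control for TGTANATA. The U12-type and adenine classes had no such control. The ribosomal RNA precursor was built by walking from 6 seed sequences through overlapping tags (19-nt overlap, at least 2 reads per step), which placed 4805 positions. Its regions were defined again once after the values were seen: at first the mature 5′ ends counted within the neighbouring regions, and no rise of ITS1 in xrn2-1 was seen; ends from 10 nt before to 3 nt after a mature 5′ end were then counted apart.

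The miRNA sites were found by pairing tags, extended upstream through overlapping tags, with 21 miRNAs fixed beforehand (G:U counted as 0.5 of a mismatch). A first search with 1-nt steps missed several families; the search used here allows steps of up to 4 nt and drops tags with a run of 8 adenines. The highest penalty was lowered from the planned 5 to 4 on the number of sites that shuffled miRNAs gave (3 to 4 against 55), before any change of a site was tested, and the limit of 5 is given as an alternative. Counts were summed over the site and 1 nt to either side, and scaled with the factors of the tag table. The stop codon share was planned over 1 to 50 nt upstream of annotated stop codons; a 20-nt tag shows only 9 to 17 nt here, in any frame.

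The tag test was tested on simulated data with counts drawn from the WT means of tags that have a WT read (dispersion 0.12; 18091 tags, of which 15599 were tested). In the 4 comparisons it recovered 4.76% to 7.14% of 2-fold, 39.1% to 45.7% of 4-fold and 94.5% to 97.8% of 16-fold changes, and called 3 to 5 unchanged tags. A first simulation with 2-fold and 4-fold changes alone recovered fewer of both; the 16-fold changes were added after it, with the test left as it was. Small changes are therefore mostly missed. Sequence before tags was read by walking 35 nt upstream (at least 2 reads per step, 3 times the next base), with 1 tag kept per group of sequences that share 16 nt.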

Results

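Parallel analysis of RNA ends (PARE) sequences the 5′ ends of uncapped, polyadenylated RNA, which are mostly intermediates of RNA decay. It was applied to rosette leaves of 21-day-old Arabidopsis thaliana (Col-0) of 5 genotypes with 2 libraries each. Besides wild type (WT), these were xrn2-1 and xrn3-3, mutants of the nuclear 5′-3′ exoribonucleases XRN2 and XRN3, xrn4-6, a mutant of the cytoplasmic exoribonuclease XRN4, and fry1-6, a mutant of the phosphatase FRY1, which removes an inhibitor of the XRN enzymes. The question was which decay fragments build up in each mutant. Each library held between 45133255 reads (fry1-6 replicate 1) and 60176505 reads (xrn3-3 replicate 1), in 8800408 to 14887798 distinct tags of 20 or 21 nt. The most frequent tag took 0.312% to 2.53% of a library. Across the tested tags, the log2 CPM (counts divided by the library total and scaled alike) of replicates correlated with r of 0.859 (xrn3-3) to 0.938 (xrn2-1), and WT with fry1-6 with r of -0.452 to -0.387. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 10.5 to 15.8. No genome was used here, so tags are described by sequence and class, not by gene, and the mutated genes themselves were not analysed here. P-values measure the spread between libraries that the labels call replicates, and that spread may be technical.

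Single 5′ ends changed on very different scales in the 4 mutants. Among 261951 tags tested against WT, 58388 rose and 284 fell in xrn3-3, and 16828 rose and 1014 fell in xrn4-6. In fry1-6, 86813 rose and 102829 fell. In xrn2-1, 114 rose and 4 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Many of the raised tags were absent from WT: 23703 of those raised in xrn3-3 (40.6%) and 24346 of those raised in fry1-6 (28.0%) had no WT read, against 77 in xrn4-6 and 21 in xrn2-1. Tags were kept for their reads over all libraries, so a tag can be tested because it is high in 1 mutant alone. The share of a class that rose is therefore partly set by this filter. The xrn2-1 count depended on single libraries. The number that rose was 0 without WT replicate 2, 5 without WT replicate 1, 17 without xrn2-1 replicate 1 and 15 without xrn2-1 replicate 2, and 0 with only the 4 libraries of both groups in the fit, whereas DESeq2 gave 883 that rose and 104 that fell. The number that fell in the other mutants also depended on single libraries: it was 56637 in fry1-6 without fry1-6 replicate 1, 359 in xrn4-6 without xrn4-6 replicate 1 and 518 without xrn4-6 replicate 2. In xrn3-3 it was 711 and 912 without WT replicate 1 and 2, and 162 and 143 without xrn3-3 replicate 1 and 2. With library totals, 944 fell in xrn3-3 and 2025 in xrn4-6, and with DESeq2 492 and 2682. The split between higher and lower tags in fry1-6 depended on the setting: 45.8% of the changed tags were higher in the fit given here and 31.9% with library totals in place of TMM factors. It was 66.8% at a minimum of 100 reads, 63.6% at 500, 69.7% with 20-nt tags alone, 73.9% with only the 4 libraries and 75.8% with DESeq2. The median log2 change of all tags in fry1-6 was -0.80 with TMM factors and -2.20 with library totals. In xrn3-3 it was -0.048 and -0.26, and in xrn4-6 0 and -0.23.

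The tags with the greatest changes rose from few or no WT reads. In xrn2-1, the tag CGGAGTTTTTTCAGCAGTTC rose from 0.83 ± 0.36 CPM in WT to 338 ± 57.3 CPM (SD, n = 2 each; log2 fold change 8.62, edgeR adjusted p = 0.0018), against 22.7 ± 4.4 CPM in fry1-6 and 3.81 ± 0.07 CPM in xrn3-3. The tag TGGCCGAGAAGAATGGGCGT rose from 0.39 ± 0.21 to 201 ± 55.2 CPM in xrn2-1 (log2 fold change 8.93, edgeR adjusted p = 0.0018). In xrn3-3, GTTCATCTCGTAATTGGCAC had no read in either WT library and 61.6 ± 24.2 CPM (n = 2), at least 2043-fold higher against a floor of 3 counts over the WT group. The xrn3-3 tag that fell most, CTCCTCCTCCTCTCGCTTCT, went from 18.3 ± 7.57 to 1.09 ± 0.44 CPM (log2 fold change -3.86, edgeR adjusted p = 0.00065). In xrn4-6, TCATCCTCGAGAAATCGAGA rose from 0.050 CPM in WT to 12.1 ± 1.67 CPM (log2 fold change 8.16, edgeR adjusted p = 0.00025), while AGACCTGAGGGCTTGATTCT fell from 15.7 to 1.75 ± 0.56 CPM (log2 fold change -2.86). In fry1-6, CTTCTTAAGCTCACTGTAAA was absent from WT and reached 194 ± 19.3 CPM, at least 6608-fold higher. CPM use library totals, while fold changes use TMM factors. Intervals and floors cover counting error only.

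Tags that begin with a 5′ splice site sequence, the first bases of an intron, built up in xrn3-3 and fry1-6. Tags starting with GTAAGT, GTATGT or GTGAGT made up 578 ± 3.32 RPM (reads scaled by the library total, as in CPM) in WT, 6407 ± 423 in xrn3-3 (11.1-fold) and 35880 ± 2513 in fry1-6 (62.1-fold; SD, n = 2 each). They made up 580 ± 30.3 RPM in xrn2-1 and 721 ± 13.1 in xrn4-6. Of 3321 such tags tested, 3131 rose in xrn3-3, and 3207 rose and 63 fell in fry1-6, with a median fitted log2 fold change of 7.04 and 11.22. In xrn4-6, 25 rose. For instance, GTATGTATCTGTCTTGAATC had no read in WT or xrn4-6, 14.6 ± 5.82 CPM in xrn3-3 and 49.1 ± 2.26 CPM in fry1-6. Such tags with few WT reads were tested only where a mutant was high, so the filter favours these counts and medians. Only 29 of the 3321 had at least 200 WT reads. Their median log2 fold over WT, by library totals, was -0.49 in xrn3-3 and -2.71 in fry1-6, with 3 above 1 in each. The shares of reads include all tags and do not rest on this filter. Tags that start with rearranged hexamers of the same bases, measured the same way, stood at 55670 ± 3688 RPM in WT, 51920 ± 1995 in xrn3-3 and 46230 ± 395 in fry1-6. Reads that begin with the start sequences of the rare U12-type introns were also more frequent in both. They were not placed on introns, and these sequences had no rearranged control. GTATCCTT starts went from 13 ± 3.91 RPM in WT to 89.7 ± 1.86 in xrn3-3 and 193 ± 8.70 in fry1-6, and ATATCCTT starts from 11.5 ± 0.042 to 30.8 ± 0.95 and 114 ± 0.028, with 21 ± 1.16 in xrn4-6. As a share of distinct tags, GTATCCTT starts stood at 1.72 times WT in xrn3-3 and 2.59 times WT in fry1-6, and ATATCCTT starts at 1.11 and 1.71 times WT, so that for ATATCCTT in xrn3-3 the difference lay mainly in reads per tag. The genotypes differed in the share of 5′ splice site starts by an exact permutation test over all ways to pair the 10 libraries (p = 0.0032, adjusted p = 0.0106 over 20 classes, one-sided by construction). The class was found by looking through these same data, and the adjustment does not cover that search. Rearranged hexamers also differed by this exact test (p = 0.019, adjusted p = 0.0423), with no mutant mean above WT. The p-value alone therefore does not set 5′ splice site starts apart. No mutant was tested alone for its share, since a permutation of a pair of libraries against another pair cannot reach a two-sided p below 0.333.

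**Figure D1:**
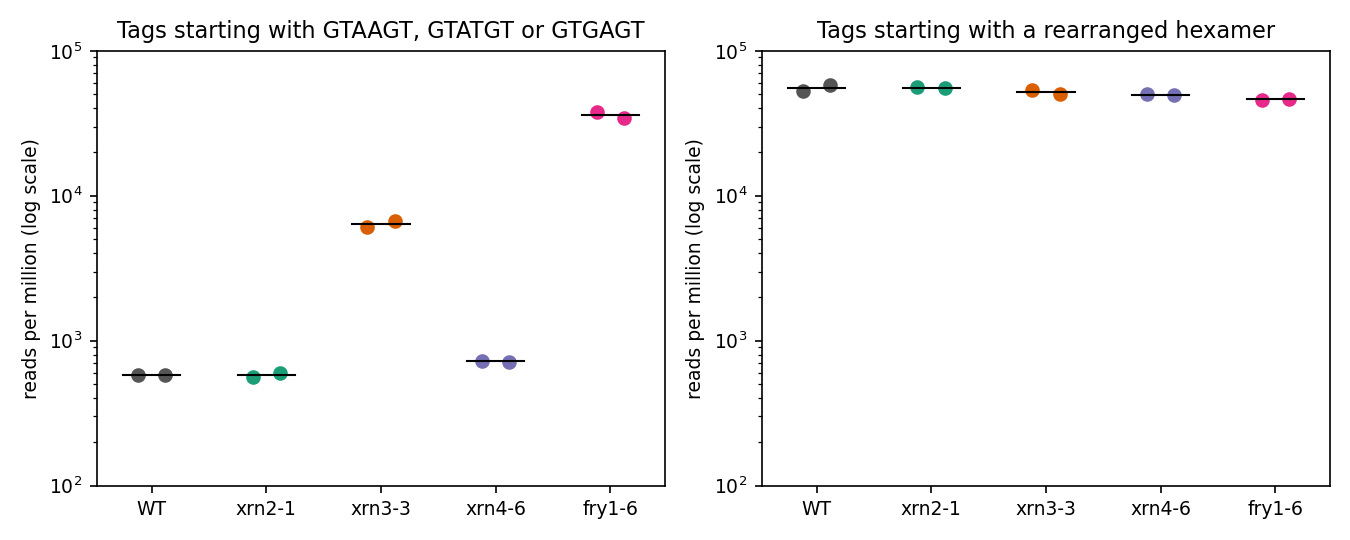
RPM (log scale) of tags that start with a 5′ splice site hexamer (left) or with a rearranged hexamer (right), per library (points) with the group mean (lines), n = 2 per genotype. Both xrn3-3 and both fry1-6 libraries lie above all WT, xrn2-1 and xrn4-6 libraries on the left, and no genotype mean lies above that of WT on the right.

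Reads within the internal transcribed spacers of the ribosomal RNA precursor were more frequent in xrn2-1 and fry1-6 than in WT, and to a lesser extent in xrn3-3. Reads in the first internal transcribed spacer (ITS1, between 18S and 5.8S) went from 59.2 ± 14.8 RPM in WT to 295 ± 33.1 in xrn2-1 (4.98-fold), 184 ± 80.6 in xrn3-3 and 603 ± 117 in fry1-6 (10.2-fold), against 69.2 ± 22.2 in xrn4-6. In the second spacer (ITS2), they went from 10.9 ± 2.81 to 49.7 ± 7.34 in xrn2-1 and 109 ± 16.4 in fry1-6. By library, ITS2 reads stood at 12.9 and 8.91 RPM in WT, 25.5 and 16.3 in xrn3-3 and 22.4 and 12.9 in xrn4-6. Within 25S they went from 2803 ± 1115 to 10040 ± 2576 in xrn2-1 and 7542 ± 1231 in fry1-6. In the part of the external spacer placed before 18S they stood at 75.2 ± 24.4 RPM in WT, 113 ± 34.6 in xrn2-1 and 84.4 ± 11.7 in fry1-6, with no difference between genotypes past the threshold (exact permutation p = 0.477). Of its 75 positions, 52 and 40 had reads in the WT libraries, 72 and 69 in xrn2-1 and 71 and 70 in fry1-6. The genotypes differed in ITS1 (exact permutation p = 0.0021, adjusted p = 0.0085) and ITS2 (exact permutation p = 0.0042, adjusted p = 0.0121), and the 25S difference missed the threshold after adjustment (exact permutation p = 0.0265, adjusted p = 0.0529). Reads at the 5′ ends of mature 18S and 5.8S RNA did not follow: they stood at 2193 ± 1151 and 3528 ± 525 RPM in WT and 2426 ± 160 and 3461 ± 947 in xrn2-1, and lower in fry1-6, at 272 ± 23.7 and 567 ± 8.48. Of the 114 tags that rose in xrn2-1, 22 lay in ITS1 and 27 in 25S. Another 65 were not placed on the precursor, and 50 of these share a 16-nt stretch with another of them. Of 74 ITS1 tags tested, 22 rose in xrn2-1, 17 in xrn3-3, 0 in xrn4-6 and 70 in fry1-6. Without single libraries, the number of precursor tags that rose in xrn2-1 went from 49 to 0 (either WT replicate), 4 (without xrn2-1 replicate 1) or 2 (without xrn2-1 replicate 2), whereas DESeq2 gave 725. The median log2 fold change over all 2093 precursor tags tested was 1.68, with DESeq2 1.66, and 2.02, 1.39, 1.46 and 1.85 without WT replicate 1, WT replicate 2, xrn2-1 replicate 1 and xrn2-1 replicate 2. It was 0.49 in xrn3-3 and 0.47 in xrn4-6. Of the precursor tags, 2.34% rose in xrn2-1, 3.92% in xrn3-3, 4.59% in xrn4-6 and 76.2% in fry1-6. Of all tags tested, 0.0435%, 22.3%, 6.42% and 33.1% rose in these mutants.

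**Figure D2:**
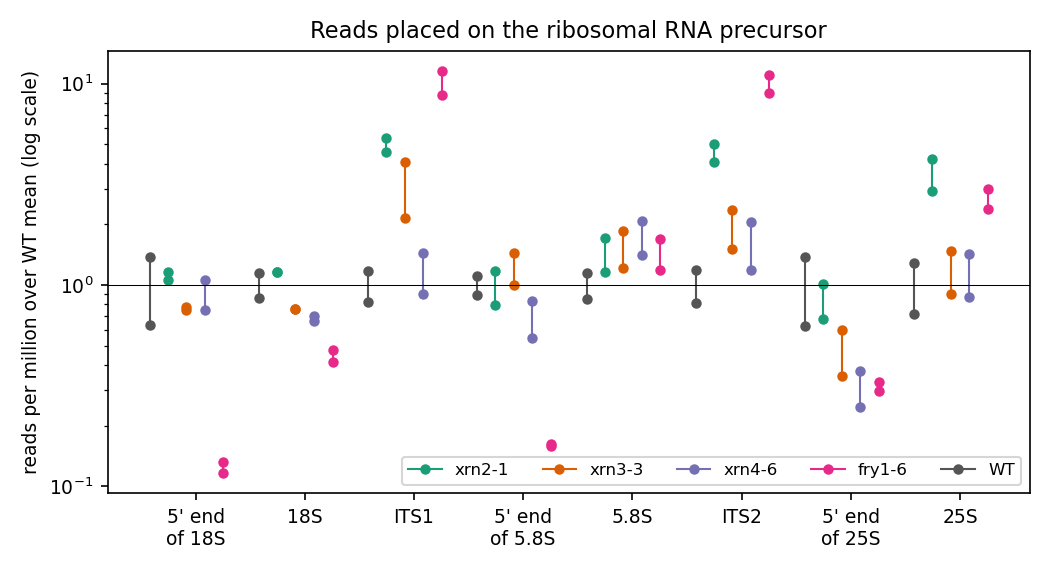
RPM in each part of the ribosomal RNA precursor, divided by the WT mean (log scale), per library (points, joined within a genotype, n = 2). Reads of both internal spacers lie above WT in xrn2-1 and fry1-6 (ITS1 4.98-fold and 10.2-fold), and less so in xrn3-3. Group means at the mature 18S and 5.8S 5′ ends are 1.11-fold and 0.981-fold in xrn2-1 and below WT in fry1-6.

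Tags at miRNA cleavage sites were more frequent in xrn4-6 and fry1-6. A search for tags that start opposite the cleavage position of 21 conserved miRNAs found 55 sites for 19 of them, against a mean of 3.4 for shuffled miRNA sequences. In xrn4-6, 23 of the 55 rose, adjusted over the list alone, with a median log2 fold change of 0.69. This count is not comparable with those of the other classes, which were adjusted over all tags. In that tag-level test, 2 of the 42 site tags tested rose in xrn4-6 (4.76%), against 6.42% of all tags. Their median log2 fold change was 0.68. Among the miR156 sites, whose targets are SPL transcription factors, 4 of 10 rose, and among the miR169 sites, whose targets are NF-YA factors, 3 of 4. With library totals, 0 of either family passed, and the miR156 median log2 fold change went from 0.66 to 0.36, and to -0.13 with DESeq2. That of miR169 went from 1.08 to 0.79 and 0.23. With TMM factors, 0 of 5 miR172 and 0 of 3 miR394 sites rose in xrn4-6, with medians of 0.47 and -0.14. For miR171, miR319 and miR403, 0 sites rose. A miR393 site went from 7.31 ± 0.82 to 20 ± 1.71 CPM (log2 fold change 1.75, edgeR adjusted p = 0.0145), and a miR159 site from 13.8 ± 2.96 to 31.6 ± 4.06 CPM (log2 fold change 1.49, edgeR adjusted p = 0.0145). The xrn4-6 calls rest on the scaling and on single libraries: 0 sites rose with library totals (edgeR; 17 at an unadjusted p under 0.05), where the median log2 change was 0.38. Without WT replicate 1, 29 rose, 1 without WT replicate 2, 7 without xrn4-6 replicate 1 and 0 without xrn4-6 replicate 2 (16 at an unadjusted p under 0.05). The median log2 fold change was 1.02, 0.59, 0.56 and 0.72 in these 4 fits. DESeq2, whose size factors here come from the sites alone, called 0 that rose and 2 that fell.

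In fry1-6, 46 of the 55 sites rose and 2 fell, with a median log2 fold change of 2.18. In the tag-level test, 36 of the 42 site tags rose in fry1-6 (85.7%), against 33.1% of all tags. The 10 miR156 sites, the 5 miR172 sites, whose targets are AP2-like factors, and the 4 miR169 sites all rose. With library totals 6, 4 and 3 of them passed the test and all lay above WT, whereas with DESeq2 4, 1 and 2 passed, and 7 miR156 and 4 miR172 sites lay above WT. A miR156 site went from 38.2 ± 16.8 to 297 ± 4.59 CPM (log2 fold change 4.37, edgeR adjusted p = 3.25e-06), and a miR172 site from 22.9 ± 1.17 to 106 ± 24.8 CPM. With library totals, 24 rose and 4 fell, with a median log2 change of 0.76, and DESeq2 called 14 and 12. The sites that fell match miR394 with penalties of 4 and 3.5 and were singled out after their values were seen; the first had 44 and 36 reads in WT and 5 and 5 in fry1-6, the other 16 and 15 in WT and 1 and 1 in fry1-6. In xrn3-3, 1 site rose, a weak match to miR396 (penalty 4) that had no WT read, 53 and 42 reads in xrn3-3 and 22 and 8 in fry1-6, at least 29.3-fold and 11.1-fold higher; it too was singled out after its values were seen. In xrn2-1, 0 sites changed by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2.

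**Figure D3:**
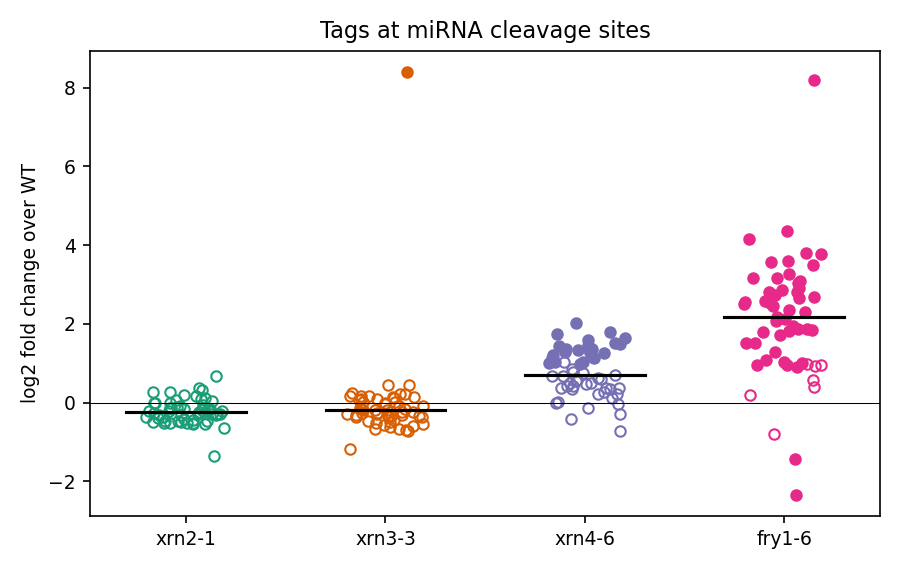
Log2 fold change over WT of the 55 miRNA cleavage sites in each mutant (TMM scaling); filled points passed an edgeR adjusted p under 0.05, and lines are medians. Medians are -0.23 in xrn2-1, -0.20 in xrn3-3, 0.69 in xrn4-6 and 2.18 in fry1-6.

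Ends 16 to 17 nt upstream of stop codons, where a ribosome at the stop codon leaves its edge, were compared through the stop trinucleotides inside tags. A read was counted once for each stop trinucleotide 9 to 17 nt from its start. Of these, 25.5% ± 0.71 (SD, n = 2) lay at 16 to 17 nt in WT, 24.7% ± 0.56 in xrn2-1, 24.3% ± 0.0014 in xrn3-3, 23.3% ± 1.42 in xrn4-6 and 22.7% ± 0.23 in fry1-6. For rearranged trinucleotides it was 18% ± 1.22 in WT and 19.9% ± 0.26 in fry1-6. The genotypes did not differ past the threshold (exact permutation p = 0.0878, one-sided by construction), but they did without xrn4-6 replicate 1 (p = 0.0392 by the same exact test) or without xrn4-6 replicate 2 (p = 0.0138 by the same exact test). Most of the printed difference lay in few tags. Without the 50 tags with most reads, the share was 23.3% and 23.1% in the WT libraries and 22.7% and 22.4% in fry1-6 (exact permutation p = 0.285). By distinct tags it was 22.4% in each WT library and 22.4% and 22.3% in fry1-6 (exact permutation p = 0.432). Stop trinucleotides in any reading frame are counted, which dilutes the share. By distinct tags it lay close to an even spread over 9 to 17 nt. The test therefore had little footprint to compare and cannot show that the genotypes are alike in it.

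In xrn4-6, tags whose 5′ end lies 2 nt before the motif TGTANATA, the recognition sequence of PUF (Pumilio) RNA-binding proteins, rose. They made up 454 ± 31.4 RPM in WT, 1971 ± 129 in xrn4-6 (4.34-fold), 436 ± 48.8 in xrn2-1, 697 ± 105 in xrn3-3 and 265 ± 10.5 in fry1-6 (SD, n = 2 each). The genotypes differed (exact permutation p = 0.0021, adjusted p = 0.0085), but this does not test xrn4-6 alone. The class was found by looking through these same data, and the adjustment does not cover that search. Of 357 such tags tested, 262 rose in xrn4-6, with a median log2 fold change of 2.48. As a share of distinct tags the difference was smaller, with xrn4-6 at 1.67 times WT, below xrn3-3 at 1.87 times WT, and fry1-6 at 1.51 times WT. The rise was not confined to this distance. From the WT to the xrn4-6 libraries, tags that start at the motif itself went from 160 and 138 RPM to 446 and 435, those 1 nt before it from 106 and 116 to 229 and 216, and those 3 nt before it from 1540 and 1165 to 2690 and 2497. With 1 base of the motif changed, 117 of 625 rose, and the reads went from 1728 ± 130 to 2438 ± 151 RPM, with 2326 ± 308 in xrn3-3 and 2410 ± 67.5 in fry1-6. The tag TATGTACATAGCCGGTTTAT rose from 0.15 to 12.3 ± 2.59 CPM in xrn4-6 (log2 fold change 6.64, edgeR adjusted p = 0.00025).

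**Figure D4:**
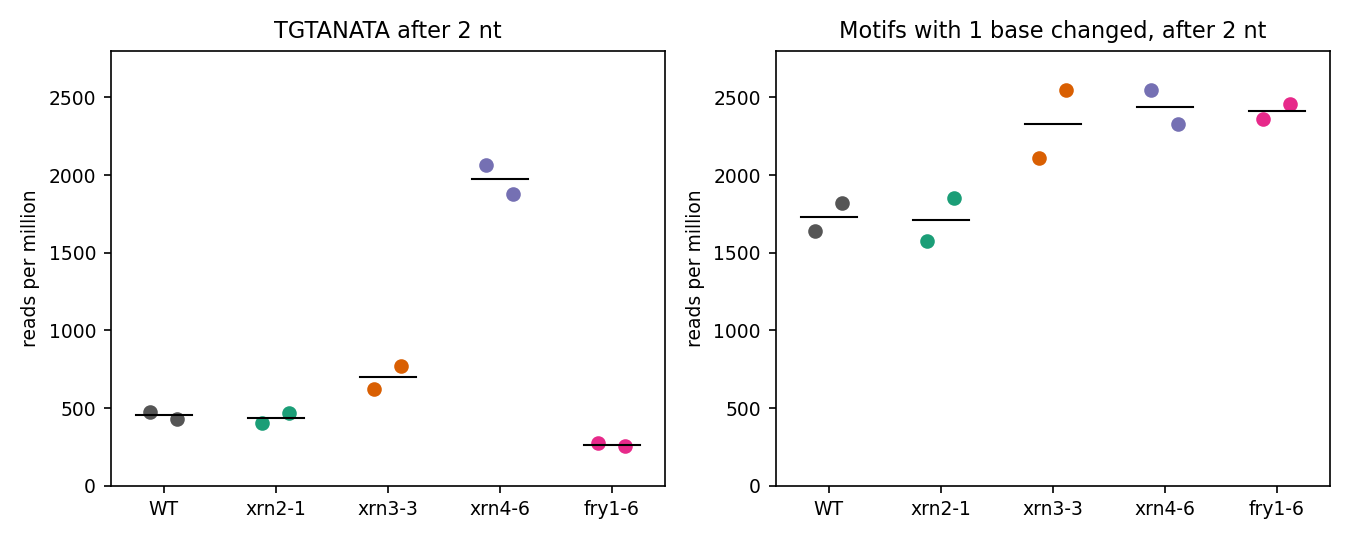
RPM of tags with TGTANATA 2 nt after their 5′ end (left) or with the same motif changed at 1 base (right), per library (points) with the group mean (lines), n = 2 per genotype. The xrn4-6 libraries stand at a mean of 1971 against 454 in WT on the left.

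Because FRY1 loss is held to impair all 3 XRN enzymes, fry1-6 was set against each xrn mutant. Of the tags that rose in xrn3-3, 57651 of 58388 (98.7%) also rose in fry1-6, where 19350 would for independent lists. For xrn4-6 it was 12550 of 16828 (74.6%; 5577 for independent lists) and for xrn2-1 111 of 114 (37.8 for independent lists). The lists of xrn3-3 and xrn4-6 shared 705 raised tags, where independent lists would share 3751. The filter on reads over all libraries admits tags that are high in 1 mutant alone, which lowers such an overlap. The numbers for independent lists do not allow for this filter, so 705 against 3751 does not show that these lists avoid each other. Across the 261951 tags, which are not independent replicates, the log2 fold changes of fry1-6 correlated with those of xrn3-3 at r = 0.897, of xrn2-1 at 0.222 and of xrn4-6 at 0.175. Unchanged groups simulated against the same WT libraries gave r of 0.459, 0.462 and 0.455. These groups lack the spread of the real fold changes, so their r is no level to set the real r against. The covariances were 12.5, 0.78 and 1.06, against 0.151 in each simulation. All comparisons share the WT libraries, so part of these overlaps may come from them. Without xrn2-1 replicate 2, r with xrn2-1 was 0.0069 and the covariance 0.031, and without WT replicate 1 the covariance was 1.53. For xrn4-6, r was 0.0971 without xrn4-6 replicate 2, and the covariance 1.92 without WT replicate 1.

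Tags that begin with at least 12 adenines stood at 8529 ± 3123 RPM in WT and 761 ± 308 in fry1-6 (SD, n = 2 each). Both fry1-6 libraries were below both WT libraries, and the genotypes did not differ past the threshold (exact permutation p = 0.0593, adjusted p = 0.0877), although p was 0.0296 without WT replicate 1 and 0.0455 without xrn3-3 replicate 2. Most of these reads came from few tags: without the 50 tags with most reads the class stood at 381 ± 72.8 RPM in WT and 67.1 ± 21 in fry1-6 (exact permutation p = 0.0762), and its share of distinct tags did not differ past the threshold (exact permutation p = 0.451). Of 67 such tags tested, 44 fell and 5 rose in fry1-6.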

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

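All tests of this part were chosen after the pattern was seen; for those on tags with at least 200 WT reads, the limits were written down before their values were computed. The tag-level tests used tags with at least 200 reads over all libraries. Among the remaining tags, which those tests do not use, reads that start with a 5′ splice site hexamer stood above the WT level in 2 mutants: 2878 ± 135 RPM of these reads in xrn3-3 and 13130 ± 278 in fry1-6, against 655 ± 5.8 in WT (SD, n = 2 each), 658 ± 19.2 in xrn2-1 and 644 ± 5.37 in xrn4-6.

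A bias of the library for the bases of the 5′ end would raise rearranged hexamers of the same bases too, but over all reads these were 0.933 times WT in xrn3-3 and 0.830 times WT in fry1-6, where the 5′ splice site hexamers were 11.1 and 62.1 times WT. The rearranged hexamers leave out words that start with GT, and of 33900 GT-start tags 21659 rose in xrn3-3 and 24060 in fry1-6. A bias for GT starts or for the hexamers would multiply tags already present in WT as well. Among the 2249 GT-start tags with at least 200 WT reads, however, the median log2 fold over WT, by library totals, was -0.47 in xrn3-3 and -2.99 in fry1-6, and among 29 with a 5′ splice site hexamer -0.49 and -2.71, against -0.50 and -3.12 for all 39095 tags with as many WT reads. A few tags taking most reads would leave the share of distinct tags at the WT level, yet that share was 2.64 times WT in xrn3-3 and 5.50 times WT in fry1-6. Without the 50 tags with most reads, the share of reads was 10.9 and 56.7 times WT. That check cannot decide this, since leaving out these 50 took away hardly any reads with a 5′ splice site start. The other values argue against all of these explanations as the whole cause. A build-up of excised introns or of unspliced fragments cut at the 5′ splice site is a hypothesis that stays open, since introns were not placed on a genome and the pattern was found and tested in the same libraries.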

How the results depend on the processing

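Alternatives of the tag and class counts and the window of 15 to 17 nt (stop codons) were chosen after seeing the data, as was the miRNA limit of 4; the planned limit of 5 is the alternative to it. With other tag filters, at 100 reads 106191 tags changed in xrn3-3 and 34566 in xrn4-6, and at 500 reads 63 in xrn2-1, 23545, 6344 and 56838 in fry1-6. Tags with a 5′ splice site start that rose were 4821 and 1528 in xrn3-3 and 5058 and 1545 in fry1-6 at these filters, and TGTANATA tags in xrn4-6 418 and 107. The number tested does not account for all of this, since at 100 reads 567696 tags were tested in place of 261951 and 90776 in place of 102829 fell in fry1-6; the cause was not tested. In fry1-6, only the 4 libraries gave 126247 changed tags; the cause was not tested. For xrn2-1, 20-nt tags alone gave 68 changed tags and DESeq2 987, and only the 4 libraries gave 0; for its precursor tags that rose these were 23, 725 and 0, and 30 at 500 reads. Leaving out 1 library gave 0 to 17 changed and 0 to 4 precursor tags in xrn2-1, 0 to 29 miRNA sites in xrn4-6, stop codon p of 0.0138 to 0.212, and r with fry1-6 of 0.0069 to 0.312 (xrn2-1), 0.873 to 0.900 (xrn3-3) and 0.0971 to 0.260 (xrn4-6); a group left with 1 library is assumed to vary like the others.

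For miRNA sites, library totals gave 0 in xrn4-6 and 28 in fry1-6, DESeq2 2 and 26, since size factors from the sites alone absorb a rise they share, and the limit of 5 gave 3 in xrn3-3 and 94 in fry1-6, of which 72 rose and 22 fell, against 46 and 2. Tags with a mean CPM of at least 10 gave r with fry1-6 of 0.50 (xrn2-1), 0.918 (xrn3-3) and 0.161 (xrn4-6). Simulated unchanged groups gave 0.473, 0.481 and 0.499. They lack the spread of the real fold changes, so their r is no level to set the real r against. The covariances were 2.68, 19.4 and 1.37, against 0.169, 0.173 and 0.177 in the simulations. The cause was not tested. As shares of distinct tags, the order of genotypes turned for 18S (exact p = 0.0042) and for the mature 5′ ends of 18S (p = 0.0582), 5.8S (p = 0.0021) and 25S (p = 0.0021). These shares decide nothing: the 5.8S and 25S ends had reads at all 14 positions in every library, the 18S end at 10 to 14 and 18S at 772 to 812 of 827, so they mainly follow the number of distinct tags per library. The order also turned for the 18S end without the 50 highest tags (exact p = 0.475); the cause was not tested. Of the 212 comparisons of main results with an alternative, 163 were labelled the same. For shares this meant the same direction and side of the threshold, and for correlations a difference below the SD of the leave-one-out values. For counts it meant a total within 1.5 times, without regard to direction. In fry1-6, DESeq2 (133095 changed tags) and 20-nt tags alone (128444) passed as the same as 189642. The percentage that was higher nevertheless went from 45.8% to 75.8% and 69.7%. Of 451 comparisons for named tags 37 lost the threshold, of 132 for named miRNA sites 27, and none of these changed sign.

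Replicate numbers are shared between genotypes, but the labels do not say that a number marks a batch. Same-numbered libraries deviated together (r of 0.141 to 0.578), a hint from the data. With the replicate block, 964 tags and 742 precursor tags changed in xrn2-1, and 1262 tags fell in xrn3-3 and 2572 in xrn4-6. With it, the exact p was 0.0063 for 25S, 0.019 for adenine starts and 0.0063 for GC-type starts. Small changes are limited by depth and by 2 libraries per genotype. The planned window of 15 to 18 nt cannot be had with 20-nt tags, and alternatives of the planned gene, intron, window, 3′ UTR, junction, frame and transcript start results were not run.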

Other observations

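Of the tests in this part, those on ribosomal RNA and on the 5′ splice site forms were chosen after the result was seen; those on rearranged words before AATAAA and on xrn4-6 and fry1-6 were written down before. As a share of reads, starts with GCAAGT, the GC-type form of the 5′ splice site, were 517 ± 75.7 RPM in WT, 651 ± 96.2 in xrn3-3 and 625 ± 90 in fry1-6, where 1 fry1-6 library lay below 1 WT library (exact permutation p = 0.0614, adjusted p = 0.0877). As single tags, 67 of 118 rose and 1 fell in xrn3-3 and 72 rose and 35 fell in fry1-6 (edgeR adjusted p under 0.05), against 571 of 7449 rearranged GC hexamers that rose in xrn3-3. Tags that start with GT and rose in xrn3-3 mostly lacked a clear tag starting 1 nt upstream (at least 2 reads and 3 times the next base). Of 20000, 84.6% had none, against 2.5% of 8729 GT tags without a call.

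Tags outside the GT class that rose in xrn3-3 were preceded by AATAAA, the main polyadenylation signal, 8 to 35 nt upstream in 159 of 3174 cases (5.01%), against 27 of 3826 (0.706%) of tags without a call, an enrichment of 7.10 (95% bootstrap interval 4.89 to 11). Enrichment of raised tags in any mutant is argued against by xrn4-6, where it was 1.08 (0.694 to 1.69). Base composition stays open: rearranged words of the same bases were enriched 3.29-fold, so that AATAAA exceeded them 2.15-fold (1.51 to 3.24) in xrn3-3 and 2.24-fold (1.60 to 3.50) in fry1-6, and both intervals include the limit of 2 set beforehand. Decay fragments from downstream of polyadenylation sites are a candidate explanation for part of the xrn3-3 tags, which placing the tags on a genome would test.

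The higher share of ITS1 reads in xrn2-1 was set against a larger carry-over of ribosomal RNA into those libraries. Carry-over would raise the 5′ ends of mature ribosomal RNAs with ITS1, but the 18S and 5.8S ends were 1.11 and 0.981 times WT in xrn2-1, where ITS1 was 4.98 times WT. This argues against carry-over as the source of the ITS1 reads; whether the 25S reads include broken mature 25S RNA was not tested. Polyadenylated precursor fragments that XRN2 normally removes remain a hypothesis, found and tested in the same libraries after the regions had been redrawn once.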
